A study of Penicillium oxalicum with 6 samples.

How the data were processed

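Messenger RNA levels were measured by RNA sequencing in 6 libraries of Penicillium oxalicum mycelium, 3 of the POX09752 deletion strain and 3 of the Ku70 control strain, grouped by the strain given in the labels. Per the labels' protocols, spores were grown on potato-dextrose agar for 6 d, about 1 g of hyphae was moved to 100 mL of medium with Avicel, which was kept at 28 °C on a shaker (180 rpm), with a stated culture time of 24 h. The titles give 2% Avicel. The growth text names only the Ku70 strain for all 6 samples. RNA was extracted with TRIzol, per the labels' protocols.

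Each deposited table holds, per the file headers, an expected count and an FPKM value (fragments scaled to gene length and to the number of mapped fragments) for 9834 gene IDs. The submitters' processing notes name BWA 0.7.10-r789, Bowtie2 2.1.0, RSEM 1.2.12 and DESeq2, without a role for each. The genome build, the gene annotation, the strandedness of counting and any read filters are not given in the sources used here. The deposited expected counts are not normalized. They are estimates in which a read that fits several genes is divided, and 2.76% to 3.24% of the IDs in a library had a value that was not whole. The FPKM values were normalized by the authors for gene length and library total: the count divided by FPKM and library total gave nearly the same length in every library (median coefficient of variation 0.087% over 5845 genes).

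The design fixed before the data were examined foresaw limma on log2(FPKM + 1), and edgeR if counts were found. Because expected counts were found, they were rounded to whole numbers and edgeR's quasi-likelihood test became the main test, with the limma fit as an alternative. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (8807 of 9834; 93 IDs had a count of 0 everywhere). Libraries were scaled by edgeR's TMM factors, which lay between 0.973 and 1.016. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of its F statistic, which can be too small where a group is close to 0. Sets of IDs with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. For a gene at 0 in one group, the fold is a bound against 3 counts over the 3 libraries of that group.

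The main test was tested on simulated data: counts for the 8807 genes were drawn from the real means, dispersions and library sizes, with 200 genes changed. It recovered 88% of the 100 genes changed 1 log2 unit and 99% of the 100 changed 3 log2 units, with 15 false calls among the unchanged genes. The simulated changes were split evenly between rises and falls. In the data 60.1% of the tested genes were called, with more rises than falls at large folds, so these rates may not hold there. The depth was 13099454 to 14115694 counts per library. Replicates differed by more than counting error in every pair, so the spread between libraries and not depth alone limits the precision. Intervals on counts cover counting error only, since no molecular identifiers are stated.

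Genes were named by a rule fixed in advance: POX09752, the 2 largest rises and the 2 largest falls among called genes whose groups do not overlap and whose higher group has a mean of at least 10 FPKM (POX09752 is itself 1 of the falls), and up to 4 changed members of each list by mean FPKM. The remaining members of the xylanase and amylase lists, POX00063, POX06601 and POX02412, were named in addition. The reference gene table used (assembly ASM172317v3, strain HP7-1) holds locus tags without product names. None of the 9834 IDs matched a tag exactly (0 matches), and the gene lengths of 9002 IDs and of the tags with the same number were unrelated (Spearman's rho 0.0016 across genes). The tables used here therefore gave no gene names or positions, and 24 planned lists built on product names were not analysed here, among them the list of conidial markers. The 3 lists of IDs recalled from published work were kept, as IDs only. The alternatives were other scalings and filters, DESeq2, limma on FPKM with other pseudocounts (0.1 and 5), scalings and variance models, the replicate letter as a block, and leaving out each library in turn.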

Results

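Gene expression was measured by RNA sequencing in mycelium of Penicillium oxalicum, a filamentous fungus that secretes enzymes which break down plant cell walls. A strain in which the gene POX09752 was deleted was compared with the Ku70 strain, the control of this series. Ku70 is a protein of non-homologous end joining, and fungal strains without it are commonly used as hosts for gene replacement. Each group had 3 libraries, all labelled as mycelium grown for 24 h with 2% Avicel, a microcrystalline cellulose. The stated purpose was to learn how the transcription factor POX09752 affects transcripts of cellulase and xylanase genes. The total expected count per library lay between 13099454 (deletion replicate 2) and 14115694 (control replicate 1), over 9834 gene IDs. Whether the 3 libraries of a group came from separate cultures was not stated, so p-values measure only the spread between these libraries.

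The deleted gene, POX09752, had an expected count of 0 in each of the 3 deletion libraries. In the control libraries it had 1568, 1375 and 1663 counts, or 46.3 ± 3.64 FPKM (SD, n = 3). Against a floor of 3 counts over the 3 deletion libraries together, this was at least 1515-fold lower in the deletion strain (edgeR quasi-likelihood test, adjusted p = 4.73e-07). The exact two-sided permutation test of log2(FPKM + 1) gave p = 0.1, the smallest that 3 against 3 libraries allow. The strain labels and this transcript did not conflict in any of the 6 libraries.

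The deletion strain and the control differed in a large part of the transcriptome. Of 8807 genes tested, 2626 were higher and 2664 lower in the deletion strain, together 5290 genes or 60.1% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With a fold change of at least 2 in addition, 1107 genes were higher and 710 lower. At 4-fold, 470 genes were higher and 253 lower, and at 16-fold, 184 were higher and 70 lower. The genes with higher transcript levels thus made up 49.6% of all changed genes, 60.9% of those changed at least 2-fold and 72.4% of those changed at least 16-fold. The first 2 shares depended on the scaling, and the third was not computed under another scaling. The first was 52.6% with total counts in edgeR, and in limma it was 52.6% on FPKM as deposited and 44.6% after quantile normalisation. The share at 2-fold in limma was 61.4% on FPKM as deposited and 53% after quantile normalisation, with 836 genes higher and 742 lower. Changed genes were not spread evenly over the ID numbers, a split examined after the values were seen. Among the 430 tested genes with the highest-numbered 5% of IDs, 42.1% were at least 2-fold higher in the deletion strain, against 11.1% of the other tested genes (two-sided Fisher's exact test across genes, p = 2.38e-56, which treats neighbouring IDs as independent although they changed together).

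**Figure D1:**
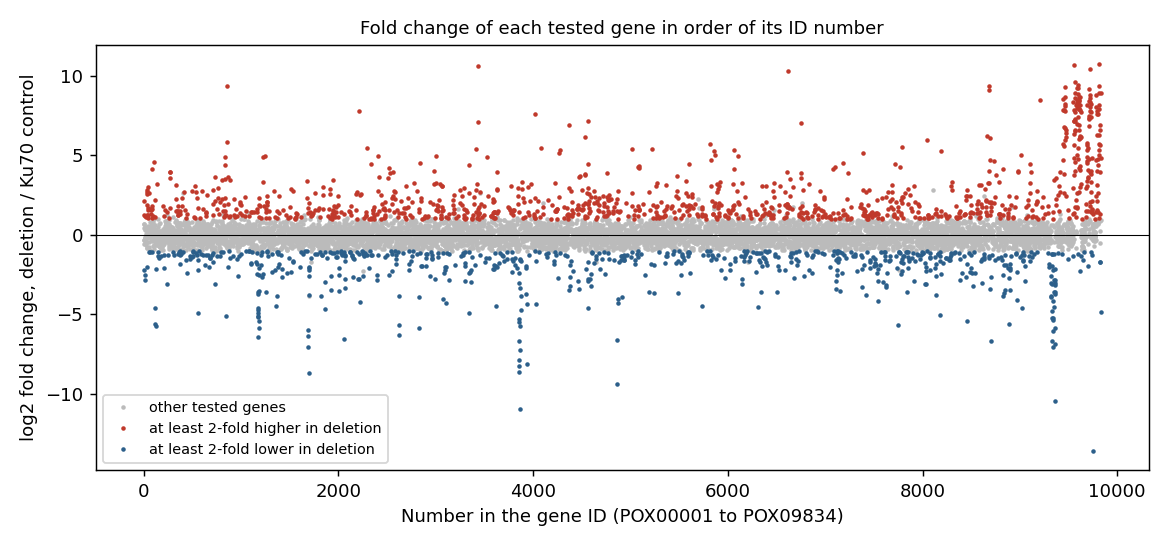
The log2 fold change (deletion over Ku70 control) of each of the 8807 tested genes is plotted against the number in its ID; red points are the 1107 genes at least 2-fold higher, blue points the 710 at least 2-fold lower, and grey points the other tested genes. At the right end, 181 of the 430 tested genes with the highest-numbered IDs are at least 2-fold higher and 30 at least 2-fold lower.

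The genes with the largest falls and rises by fitted log2 fold change were expressed in one strain and close to 0 in the other. Where a group was at 0, this rank rests on the fit, since the counts give only a bound. POX03867 had 626 ± 40.4 FPKM in the control and 0.32 ± 0.08 FPKM in the deletion strain (SD, n = 3 each), a log2 fold change of -10.92 (adjusted p = 1.73e-08, edgeR). With 20 counts over the deletion libraries, the ratio of the counts scaled to library size was 1977. Its 95% exact binomial interval, from 1280 to 3238, covers counting error only. The SE from the F statistic, 0.17, was smaller than this counting error implies, and DESeq2 gave an SE of 0.339. POX09811 was not detected in any control library and stood at 161 ± 47.6 FPKM in the deletion strain (SD, n = 3), from 638 counts over the deletion libraries. This is at least 216-fold higher against a floor of 3 counts over the control libraries (adjusted p = 3.26e-05, edgeR). It had fewer counts than POX09556 at a higher FPKM, which is scaled to gene length. POX09556 had 2221 counts over the deletion libraries and 1 count over the control libraries. Its level was 106 ± 60.8 FPKM in the deletion strain (SD, n = 3), and the ratio of the counts scaled to library size was 2251, with a 95% exact binomial interval from 404 to 88950 that covers counting error only (adjusted p = 1.88e-05, edgeR). That 1 count lay in control replicate 2, and without this library the gene was at 0 in the control and its fitted log2 fold change, which is then no bound, went from 10.67 to 12.54. The 3 deletion libraries ranged from 57.7 to 174 FPKM for POX09556 and from 115 to 210 FPKM for POX09811. What these IDs encode was not known from the tables used here.

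To address the question about cellulase and xylanase genes, 3 short lists of IDs were used that had been recalled from published work on this fungus before the data were examined. No annotation that pairs these IDs with products was used here, so the lists' names rest on that recollection alone. Of 11 IDs recalled as cellulase genes (cellobiohydrolases, endoglucanases and beta-glucosidases, which cut cellulose and its fragments), 9 were tested. In the deletion strain 6 were higher, 1 was lower and 2 did not pass the test (edgeR, adjusted p under 0.05), and 7 passed when adjusted over the list alone. Of all 8807 tested genes, 2626 were higher and 60.1% were called in either direction, so 7 calls among 9 IDs are no result about the list. The 6 became 3 with quantile normalisation in limma, and 2 where a mean of at least 5 FPKM was required and fewer members were tested. Most of these IDs were expressed at low levels: 8 of the 11 had a mean under 5 FPKM in the control, although the libraries are labelled as grown on cellulose.

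POX06835 had the strongest response on this list, with 247 ± 23.4 FPKM in the deletion strain and 26.3 ± 0.73 FPKM in the control (SD, n = 3 each). That is a 9.17-fold difference, or 3.20 ± 0.10 on the log2 scale (SE, adjusted p = 2.1e-07, edgeR). POX05571 rose from 1.54 ± 0.12 to 5.55 ± 0.43 FPKM and POX01896 from 3.25 ± 0.28 to 7.72 ± 1.15 FPKM (SD, n = 3; adjusted p = 3.58e-05 and 0.000275, edgeR). POX03641 went the other way, at 10.6 ± 1.45 FPKM in the deletion strain and 15.5 ± 0.92 FPKM in the control (SD, n = 3; adjusted p = 0.00292, edgeR). The set test with a preset correlation found the list higher than other genes (camera, adjusted p = 0.0182 over 2 lists), and this call was lost with an estimated correlation (adjusted p = 0.13).

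Of 4 IDs recalled as xylanase genes, which encode enzymes that cut the hemicellulose xylan, 2 passed the expression filter and both changed, in opposite directions. POX06783 fell from 31.5 ± 2.17 FPKM in the control to 5.29 ± 0.80 FPKM in the deletion strain (SD, n = 3 each), a 6.07-fold difference (log2 fold change -2.60 ± 0.14, SE; adjusted p = 2.5e-06, edgeR). POX08484 rose from 25.7 ± 1.13 to 34.5 ± 3.42 FPKM (SD, n = 3; log2 fold change 0.39 ± 0.10, SE; adjusted p = 0.011, edgeR). The remaining IDs of this list, POX00063 and POX06601, had 0.52 and 0.18 FPKM in the control and 0.40 and 0.12 FPKM in the deletion strain, below the filter. Both tested members also passed when adjusted over the list alone, and no set test was run on fewer than 3 tested members. Since 60.1% of all tested genes were called, 2 calls do not set this list apart from other genes.

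The 3 IDs recalled as amylase genes, whose enzymes break down starch, were among the strongly expressed genes of the control, at or above the 96.5th percentile of all IDs. POX01356 fell from 1127 ± 106 FPKM in the control to 52.9 ± 20.4 FPKM in the deletion strain (SD, n = 3 each), a 21.8-fold difference (log2 fold change -4.45 ± 0.32, SE; adjusted p = 1.2e-05, edgeR). POX09352 fell from 557 ± 38.6 to 46.6 ± 17.3 FPKM (SD, n = 3), a 12.2-fold difference (log2 fold change -3.61 ± 0.28, SE; adjusted p = 1.8e-05, edgeR). POX02412 did not pass the test, with 459 ± 32.6 FPKM in the control and 511 ± 189 FPKM in the deletion strain (SD, n = 3; adjusted p = 0.707, edgeR). Without deletion replicate 3, whose POX01356 and POX09352 levels of 29.4 and 27.5 FPKM were the lowest of the 6 libraries, POX02412 passed the test as higher (log2 fold change 0.41 ± 0.09, SE; adjusted p = 0.0015, edgeR). In all, 0 of the 3 were higher and 2 lower over all tested genes, and 2 passed when adjusted over the list alone. With 60.1% of all tested genes called, 2 calls among 3 IDs are no result about the list. The set test placed the list below other genes with a preset correlation (camera, adjusted p = 0.0182) and not with an estimated one, which was 0.852 (camera, adjusted p = 0.22).

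**Figure D2:**
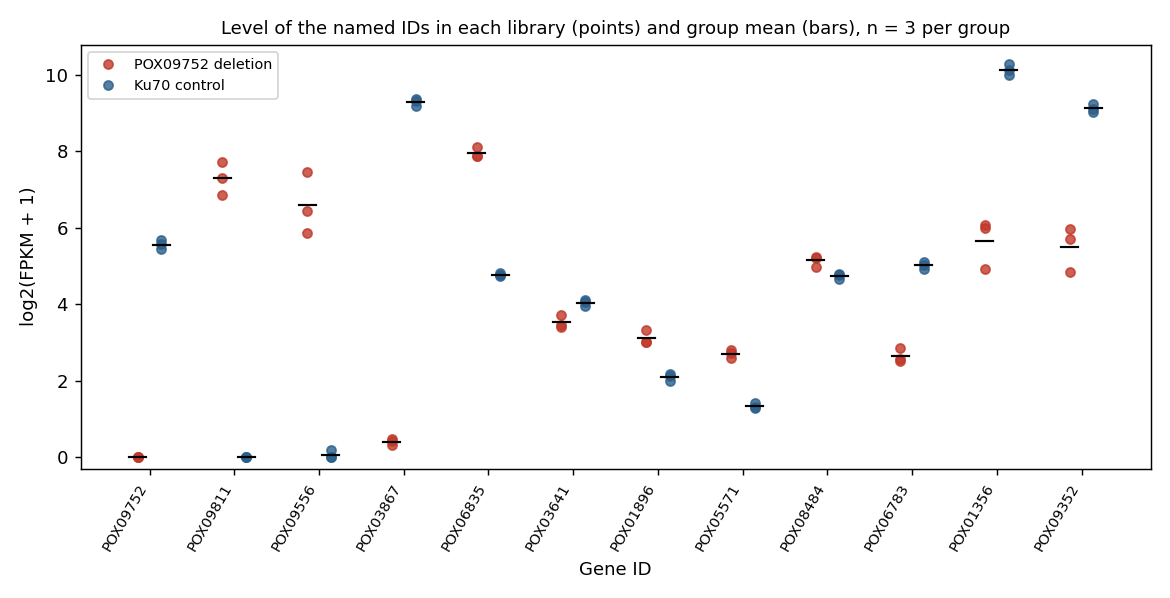
Levels of the named IDs are shown as log2(FPKM + 1) for each library (points, 3 per group) with the group mean as a black bar; red is the POX09752 deletion strain and blue the Ku70 control. POX09752 lies at 0 in the 3 deletion libraries, while POX01356 has a mean of 52.9 FPKM in the deletion strain against 1127 FPKM in the control.

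Libraries of a group resembled each other more than libraries of the other strain. Pearson's r of log2(FPKM + 1) across genes was 0.994 to 0.995 between control libraries, 0.974 to 0.991 between deletion libraries and 0.828 to 0.851 between strains. Genes are not independent replicates, so these coefficients describe the libraries and were not tested. The first principal component held 90.9% of the variance and separated the strains, and the second, with 5.2%, set deletion replicate 3 apart from the rest. Replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 7.02 to 11 between control libraries, 11.9 between deletion replicates 1 and 2, and 76.7 or more for pairs with deletion replicate 3. No library was therefore treated as a repeat deposit of another.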

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

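The count of changed genes ran from 4454 (without control replicate 3) to 5851 (without deletion replicate 3) over the 24 alternatives to the main value of 5290, and no gene called under both the main fit and an alternative had opposite signs in them. Other edgeR scalings gave 5243 to 5286 genes, DESeq2 5099 (1 adjusted p not given) and limma on log2(FPKM + 1) 5229. Scaling moved the median log2 fold change of all tested genes from 0.007 to at most 0.041 in edgeR, and in limma from 0.032 to -0.06 under quantile normalisation. Under that normalisation 2315 genes were higher and 2878 lower, and with total counts in edgeR 2759 were higher and 2484 lower. Genes changed at least 2-fold numbered 1817, and 1766 to 1926 with a library left out; with limma and a pseudocount of 5 they numbered 1161, of which 684 were higher in the deletion strain, because that pseudocount shrinks the fold changes of low genes. Of the 310 values for the named genes under an alternative, 307 kept their direction and their side of the threshold. The exceptions are all of POX02412, whose log2 fold change of 0.12 ran from -0.062 without deletion replicate 1 to 0.409 without deletion replicate 3, with a call only in the latter. Of the IDs recalled as cellulase genes, 6 were higher in the main fit, 5 to 6 with a library left out, and 2 where a mean of at least 5 FPKM was required (edgeR and limma), since fewer members were then tested; quantile normalisation gave 3, and the cause was not tested. Among the IDs recalled as amylase genes 0 to 1 were higher with a library left out, the 1 being without deletion replicate 3. The camera calls for both lists ended with an estimated correlation, at adjusted p = 0.13 (cellulase IDs, estimate -0.00206) and adjusted p = 0.22 (amylase IDs, estimate 0.852). Only the second estimate lay above the preset 0.01, so a higher correlation was not what ended the call for the cellulase IDs. The fry test, which tests the lists against no change and not against other genes, gave adjusted p = 4.32e-05 and 0.000855. The replicate letters F, S and T did not clearly pair the samples, and pairing could not be excluded. Deviations of libraries with the same letter correlated at -0.017, 0.156 and 0.075, against -0.129 to 0.063 for different letters. Not every library correlated best with its own letter. With the letter as a replicate block 5283 genes were called by edgeR and 5119 by limma. Depth limits some of the recalled IDs: POX05587 had 25 counts over the control libraries together. It was called higher, at 2.06 ± 1.41 FPKM in the deletion strain and 0.36 ± 0.1 FPKM in the control (SD, n = 3; adjusted p = 0.00678, edgeR). This 5.43-fold rise was larger than those of POX05571 and POX01896 but varied widely between the deletion libraries.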

Other observations

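The tests of replicate splits, of gene length and of carry-over counts were fixed before their results were seen, and the other tests in this part were chosen after the values had been seen. A set of 121 genes had a mean under 1 FPKM in the control and of at least 5 FPKM in the deletion strain. Because these limits select large differences in the same libraries, it is no separate support that each of the 121 genes passed the main test. Their median level was 11.6, 19.4 and 27.4 FPKM in deletion replicates 1, 2 and 3 and 0.20 to 0.24 FPKM in the control libraries. Together they took 0.313% to 0.559% of the counts of a deletion library and 0.003% of those of a control library. The opposite set, under 1 FPKM in the deletion strain and at least 5 FPKM in the control, held 28 genes, with medians of 10.2 to 12.2 FPKM in the control libraries. Without deletion replicate 3 the sets held 115 and 26 genes. Limits of 0.5 and 10 FPKM gave 59 genes for the first set, and limits of 2 and 5 FPKM gave 190.

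Genes with neighbouring ID numbers changed together. Across genes, which are not independent replicates, the log2 fold changes of IDs 1 apart correlated at r = 0.50 against at most 0.044 in 10000 shuffled orders, and at r = 0.32 without the highest-numbered 5% of IDs. The correlation was 0.23 for IDs 10 apart and 0.05 for IDs 200 apart. There were 15 runs of at least 5 consecutive IDs that were all at least 2-fold higher, holding 135 genes, and 6 such runs that were all at least 2-fold lower, holding 47 genes. The most in 1000 shuffled orders were 2 and 1 runs. The longest run of higher genes had 23 IDs and the longest run of lower genes 11, and POX03867 lay in a run of 6 lower genes. Without the highest-numbered 5% of IDs, 3 runs of higher and 5 runs of lower genes were left. If ID numbers follow the order of genes in the genome, which could not be checked here, these runs may be groups of neighbouring genes that respond together, as a hypothesis.

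The genes that were near 0 in the control gathered among the highest-numbered IDs: 71.9% of the 121 members (87 genes) lay in the highest-numbered 5% of IDs, which hold 4.9% of tested genes (Fisher's exact test across genes, p = 3.66e-89, odds ratio 62.2). Of the opposite set, 4 of the 28 genes lay there (14.3%; Fisher's exact test, p = 0.0454, unadjusted and chosen after the values were seen), too few for a conclusion. Both p-values treat genes as independent although neighbouring IDs changed together, so they are likely too small. The tables argue against reads divided between near-identical copies as the whole cause, since only 17.4% of the members had a fractional count in any library (95% exact binomial interval 11.1% to 25.3%), against 11.2% of all IDs. Absence of all members from the control strain, with its counts carried over from the deletion libraries at a single rate, is argued against by the control counts. These were not proportional to the deletion counts (chi-square per degree of freedom 39.2 over 82 members, 20.5 without the 5 that contributed most, against a simulated bound of 1.34). The test took the members together, so absence of some of them stays open. The 87 members among the highest-numbered IDs were not tested apart, nor were reads of related sequences landing on missing genes. Reads of another organism in the deletion cultures stay open. A neighbouring ID with at least 5 FPKM in the control was found for 46.3% of the members and 91.7% of all IDs. For the members among the highest-numbered IDs the share was 35.6%. Both member shares lie between the limits of 25% and 50% chosen for and against it. These limits need ID numbers to follow the order of genes in the genome, which could not be checked, and sequences were not used here. A response to the loss of POX09752 stays open too, as does any other difference between the strains.

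The test called 5290 of 8807 genes changed. The 3 other scalings moved the median log2 fold change only from 0.007 to at most 0.041, so a larger scaling error was not tested. The lowest count under them was 5243, so the choice among these scalings was not what gave so many calls. Each of these uses a single factor per library and none measures total RNA, so a difference in total RNA between the strains was not tested. Of the 10 splits of the 6 libraries, 1 gave as many genes, the real one, and the same held for genes changed at least 2-fold (1 of 10, real value 1817); the highest other split gave 0 genes by edgeR and 0 by limma in both cases, with at most 179 genes at an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.05. Every other split put libraries of both strains in each group, so the strain difference widened the spread within the groups. Few calls in those splits were therefore set in advance, and their 0 calls do not measure the rate of false calls. The labels name 0 batches, so none was tested. A response to the loss of POX09752 stays open, as does any other difference between the strains.

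Deletion replicate 3 stood apart from the other deletion libraries, with 269 of 8320 genes (3.2%) at least 2-fold from the mean of the other two, against 2.0% for replicate 1, 0.7% for replicate 2 and at most 0.1% for any control library. In replicate 3, 55 genes that fell at least 16-fold in replicates 1 and 2 were lower still (median log2 difference -0.16, 95% bootstrap interval -0.23 to -0.05). These genes also had to be called in the main fit, which includes replicate 3, and to pass a count floor in replicates 1 and 2. Both can lower the median, so it does not decide whether control RNA was mixed into this library. The POX09752 count of replicate 3 was 0, against 1375 to 1663 in the control libraries, which argues against such a mixture. The depth of replicate 3 was 1.02 times that of the other deletion libraries, which argues against depth. Its differences from the mean of the other two showed no trend with gene length (Spearman's rho 0.01 across 8320 genes), which argues against a length bias as what sets it apart, while replicates 1 and 2 differed from each other with length (rho 0.21). A difference in culture growth was not tested and stays open, and whether this library came from a culture of its own was not stated.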
